A study of Arabidopsis thaliana with 18 samples.

How the data were processed

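The deposited scanner files hold 1 array per sample, 18 in all, from whole seedlings of Arabidopsis thaliana. Per the file headers they were made with Agilent Feature Extraction, and the processed signal is an intensity, background-subtracted and detrended within the array with no normalization between arrays. The mean signal and the background signal of each spot are also intensity values per the file headers, without further processing. The other columns used are flags of 0 or 1 per the file headers, which mark spots well above background, saturated or not uniform. The deposited matrix is in log2 units, and on each array it equalled the log2 processed signal, averaged over the spots of a probe, minus a constant that puts its 75th percentile at 0, within 0.001 for at least 99.99% of probes. Per the labels RNA was total RNA from seedlings of 3 genotypes with 0 mM or 200 mM NaCl for 24 h, labelled with Cy3. The groups follow the labels, with 3 arrays in each of 6 groups, and no array was moved or left out of the main comparisons.

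The array holds 45220 spots, 43803 of them not controls, for 43603 probes. A locus code came from the systematic name for 38413 probes and from the gene name for 644, which left 4546 probes without a code. Of 29043 locus codes 28608 (98.5%) are in the TAIR10.1 gene table. The 75th percentile of the log2 processed signal over non-control probes was subtracted on each array, after spots marked as outliers were dropped and the others averaged. Each gene was represented by its probe with the highest mean, probes named by systematic name first, since 7744 codes had more than 1 probe. Genes well above background on all 3 arrays of at least 1 group were kept, 22975 in all, and 6068 were left out. Outlier spots left 2798 missing values in 1141 genes, so 22831 to 22962 genes were tested per comparison. Arrays have no read depth: 74.5% to 77.9% of probes were well above background, 2 spots were saturated in all, and the log2 difference between replicates had an SD of 0.201 to 0.935 over the 18 replicate pairs.

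One linear model with 6 group means was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3, with version 1.17.8 of the data.table package (12 residual degrees of freedom, 13.9 in total after moderation). There were 11 comparisons: salt against control in each genotype, each mutant against WT and against the other mutant in each condition, and the difference between each mutant's salt response and that of WT. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 and a change of at least 2-fold. Where a group had no array above background, the fold is given as a bound. On each array of that group the bound uses the gene's signal or, if higher, the lowest signal of any probe well above background. It can thus be smaller than the fold between the levels printed beside it. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 36 lists and 9 comparisons (324 tests), and beside it with an estimated correlation and with fry. The 36 lists hold 616 genes, of which 615 are on the array and 603 were tested. They cover type-A response regulators, cytokinin oxidases, cytokinin synthesis and relay, phenylpropanoid, flavonol and anthocyanin synthesis, lipid remodelling, phosphate, iron and nitrate responses, fatty acid, triacylglycerol, wax and suberin synthesis, abscisic acid, jasmonate, salicylic acid and auxin, ion transport, aquaporins and osmolytes. They also cover reactive oxygen, glutathione transferases, heat shock, photosynthesis, senescence, cell division, wall loosening, glucosinolates, reference genes, and root, seed, vascular and stomatal markers.

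The lists, thresholds, tests, most alternatives and the rule for naming genes were fixed before the data were examined. The rule takes the targeted genes in every group, the 8 largest called changes in each direction whose arrays do not overlap (3 against 3 arrays separate so by chance in 10% of genes) and up to 3 bounds in each direction. It also takes up to 4 called members in the direction of each list past camera and 1 in the other direction, up to 4 type-A regulators and cytokinin oxidases whether called or not, and any list gene as not called. The text names a part of these, by the symbols of the lists, which for some genes differ from those of the gene table, with the locus code at first mention. The alternatives were 4 other scalings or processed values, 2 other filters, the mean over probes, the slide as a random or fixed block, the replicate block, a trended and robust variance, array weights, fits on the compared groups alone, 2 other thresholds and each array left out in turn. Fits with the scan day as a block were added after seeing the data. The fit without the array labelled ahp2,3,5 salt replicate 3 is 1 of the planned fits that leave out an array, and it was applied to the gene lists and set beside the results after seeing the data.

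The methods were tested on simulated data with 200 of 22975 genes changed. For the WT salt comparison 57 of 67 genes changed by 1.5 log2 units were called (85.1%), 64 of 67 at 2 units and 64 of 66 at 3 units, with 2 unchanged genes called. A shift of 1 log2 unit in the phosphate list was found by camera at an adjusted p of 6.5e-31, with 0 of the other list tests past the threshold. The simulated genes varied independently of each other and without a slide effect. The test therefore does not show how camera at its preset correlation behaves where genes of a list vary together. Shared effects of both mutants were set against 100 simulations of unchanged mutants. In each, WT and mutant values were drawn from each gene's spread within its groups, and both mutants were compared with the same simulated WT values. Probes without a locus code were left out of the gene comparisons and counted apart.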

Results

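Total RNA from whole Arabidopsis thaliana seedlings was measured on 1-colour Agilent arrays, 1 sample per array. Seedlings of the wild type Col-0 (WT), of the arr1,10,12 mutant and of the ahp2,3,5 mutant were 11 days old. They had been grown for 10 days and then kept for 24 h with 0 mM NaCl (control) or 200 mM NaCl (salt). ARR1, ARR10 and ARR12 are type-B response regulators, the transcription factors at the end of the cytokinin signalling relay, and AHP2, AHP3 and AHP5 are the phosphotransfer proteins upstream of them. The 18 arrays fall into 6 groups of 3. Values are log2 signal relative to the 75th percentile of each array, group values are mean ± SD with n = 3 arrays unless another n is given, and changes come from limma with Benjamini-Hochberg adjusted p. A gene was called at an adjusted p under 0.05 and a change of at least 2-fold.

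On each array 74.5% to 77.9% of probes were well above background, and the 75th percentile of the processed signal was 3338 to 5040. Of the genes on the array, 22975 were detected on all 3 arrays of at least 1 group and 6068 were not. The number of arrays limits the precision. The design text describes 3 replicate hybridizations for each independent biological sample, so the p-values may measure only technical spread. The files name no genome build, so genes are given by symbol and locus code without positions. The first principal component held 43.7% of the variance and the second 33.1%, over 21834 genes measured on every array. On the first component the WT control arrays lay at -99.8 to -98.7 and the mutant control arrays at -37.4 to -20.9. The WT salt arrays lay at 29.3 to 37.9 and the arr1,10,12 salt arrays at 81.5 to 97.2. The array labelled ahp2,3,5 salt replicate 3 lay at -34.1, among the mutant controls, while replicates 1 and 2 of that group lay at 84.9 and 65.9. It was kept under its label. Some totals, folds and list results are also given without it, while the member counts of lists and the counts shared between genotypes include it.

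**Figure D1:**
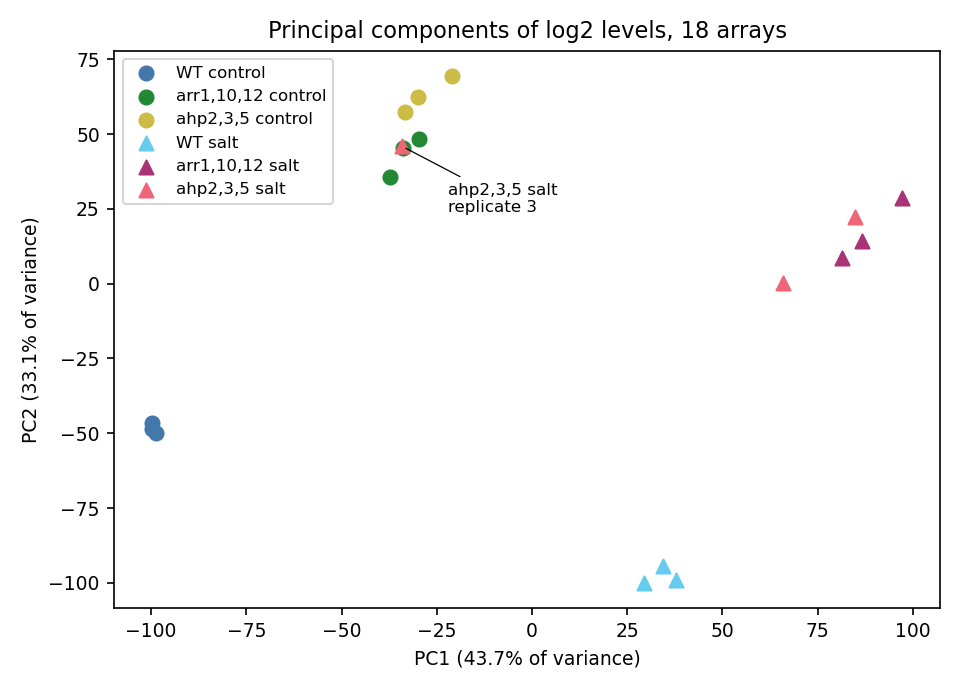
Scores of the 18 arrays on the first (43.7% of the variance) and second (33.1%) principal components of 21834 genes, with 1 point per array and 1 colour per group. The array labelled ahp2,3,5 salt replicate 3 lies at -34.1 on the first component, and the other 2 arrays of its group lie at 84.9 and 65.9.

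The 6 mutated genes were low in the mutant named after them and not in the other genotypes. AHP2 (AT3G29350) was at 0.24 ± 0.06 in WT control, 0.24 ± 0.05 in arr1,10,12 control and -3.43 ± 0.12 in ahp2,3,5 control, and at 0.16 ± 0.05, 0.05 ± 0.08 and -3.87 ± 0.39 in the same genotypes with salt. AHP3 (AT5G39340) was at 0.82 ± 0.02, 0.96 ± 0.11 and -5.34 ± 0.35 in the controls and at 0.17 ± 0.03, 0.56 ± 0.06 and -6.15 ± 0.31 with salt. AHP5 (AT1G03430) was at -2.80 ± 0.07, -3.35 ± 0.09 and -7.61 ± 0.22 in the controls, with 2 of the 3 ahp2,3,5 arrays above background, and at -3.41 ± 0.07, -3.82 ± 0.04 and -7.24 ± 0.52 with salt. ARR1 (AT3G16857) was at 0.21 ± 0.01 in WT, 0.50 ± 0.08 in ahp2,3,5 and -3.21 ± 0.31 in arr1,10,12 without salt, and at 0.04 ± 0.03, 0.28 ± 0.19 and -3.99 ± 0.21 with salt. ARR10 (AT4G31920) was at 0.91 ± 0.07, 0.09 ± 0.06 and -5.23 ± 0.28 without salt, and at 0.33 ± 0.03, -0.04 ± 0.07 and -5.94 ± 0.10 with salt. ARR12 (AT2G25180) was at 0.13 ± 0.04, -0.22 ± 0.11 and -7.08 ± 0.22 without salt, and at -1.17 ± 0.08, -0.48 ± 0.35 and -7.88 ± 0.52 with salt, where 2 of the 3 arr1,10,12 arrays were above background.

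WT seedlings with and without salt were compared to ask which transcripts follow the salt treatment when the cytokinin relay is intact. Genes called higher included 23 of 31 abscisic acid response, 12 of 17 anthocyanin, 12 of 27 jasmonate and 7 of 15 heat shock genes, and those called lower 10 of 40 photosynthesis, 12 of 21 cell division and 16 of 23 root marker genes. These lists passed camera at its preset correlation, with adjusted p = 0.72 to 0.75 with an estimated correlation. Among the largest rises was that of the lipid transfer protein gene LTP4 (AT5G59310), from -5.34 ± 1.02 to 3.89 ± 0.14 (600-fold, adjusted p = 1.7e-05). The heat stress factor gene HSFA6B (AT3G22830) rose from -5.08 ± 0.02 to 1.23 ± 0.19 (79.2-fold, adjusted p = 1.4e-06) and the mannan synthase gene CSLA01 (AT4G16590) rose 107-fold. Among the genes that fell most were those of the iron-deficiency transcription factors BHLH38 (AT3G56970, 281-fold lower, from 0.25 ± 0.56 to -7.89 ± 0.38) and BHLH101 (AT5G04150, 146-fold lower, from 0.31 ± 0.32 to -6.89 ± 0.50). Their relative BHLH100 (AT2G41240) was at least 513-fold lower, since no salt array detected it. The cytochrome P450 gene CYP82C2 (AT4G31970) fell 54.3-fold.

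Of the 31 measured abscisic acid response genes 23 rose and 0 fell, including TSPO (AT2G47770, 55.9-fold, adjusted p = 1.3e-06), LEA7 (AT1G52690, 46.2-fold, and 71-fold without WT control replicate 1) and LEA4-5 (AT5G06760, 32-fold). The phosphatase gene HAI3 (AT2G29380), above background on 2 of the 3 control arrays, had a fitted change of 57.4-fold. In the anthocyanin list 12 of 17 rose, among them the MYB activator PAP1 (AT1G56650, 6.76-fold, from -1.96 ± 0.29 to 0.79 ± 0.34), the reductase DFR (AT5G42800, 5.39-fold, adjusted p = 6.5e-08) and the glycosyltransferase UGT79B1 (AT5G54060, 5.09-fold), while PAP2 (AT1G66390), above background on 1 of the 3 control arrays and 0 of the 3 salt arrays, was called lower. Of 27 jasmonate genes 12 rose and 4 fell. CORI3 (AT4G23600) rose 12.3-fold, JAZ7 (AT2G34600) 9.39-fold and JAZ5 (AT1G17380) 4.95-fold. Heat shock genes rose in 7 of 15 cases, with HSFA2 (AT2G26150) 11.7-fold higher and HSP17.4 (AT3G46230) at a log2 change of 2.72 (2.09 and 3.5 without WT control replicates 1 and 2). In the wax list 4 of 20 rose, with WSD1 (AT5G37300) 3.76-fold and CER1 (AT1G02205) 3.39-fold higher.

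Light harvesting, photosystem and carbon fixation genes fell in 10 of 40 cases and rose in 0, with LHCB4.2 (AT3G08940) going from 6.49 ± 0.06 to 4.76 ± 0.19 (3.34-fold lower, adjusted p = 3.6e-08) and the carbon fixation gene PRK (AT1G32060) changing by -1.57 on the log2 scale. Cell division genes fell in 12 of 21 cases, including the mitotic cyclin genes CYCB1;1 (AT4G37490, 2.63-fold lower) and CYCB1;2 (AT5G06150, log2 -1.44). Of 23 root markers 16 fell, with the Casparian strip gene CASP1 (AT2G36100) going from 1.04 ± 0.02 to -1.05 ± 0.24 (4.25-fold lower) and CASP5 (AT5G15290) and RCI3 (AT1G05260) changing by -2.18 and -2.01 on the log2 scale. Of the 10 iron deficiency and ferritin genes 6 fell, with a median log2 of -4.79, but the list missed the threshold (camera adjusted p = 0.12). Camera gave adjusted p of 4.3e-10 for photosynthesis, 3.8e-09 for abscisic acid response, 8e-04 for cell division, 0.0014 for anthocyanin, 0.0057 for jasmonate, 0.0081 for root markers, 0.013 for heat shock and 0.048 for wax. With an estimated correlation none of these 8 lists passed, at adjusted p = 0.72 to 0.75. The counts of these 8 lists adjusted over the list alone were the same.

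In total 4992 of 22841 genes were called, 1758 higher and 3234 lower. All WT control arrays were scanned on the first day and all WT salt arrays on the second, with 1 ahp2,3,5 control array scanned among the latter, and with the slide as a fixed block 1845 genes were called. No slide held both WT groups, so this block links them through lone control arrays of the mutants. The lower count may thus reflect lost precision as well as any slide effect. With normexp and quantile normalization 3236 were called.

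**Figure D2:**
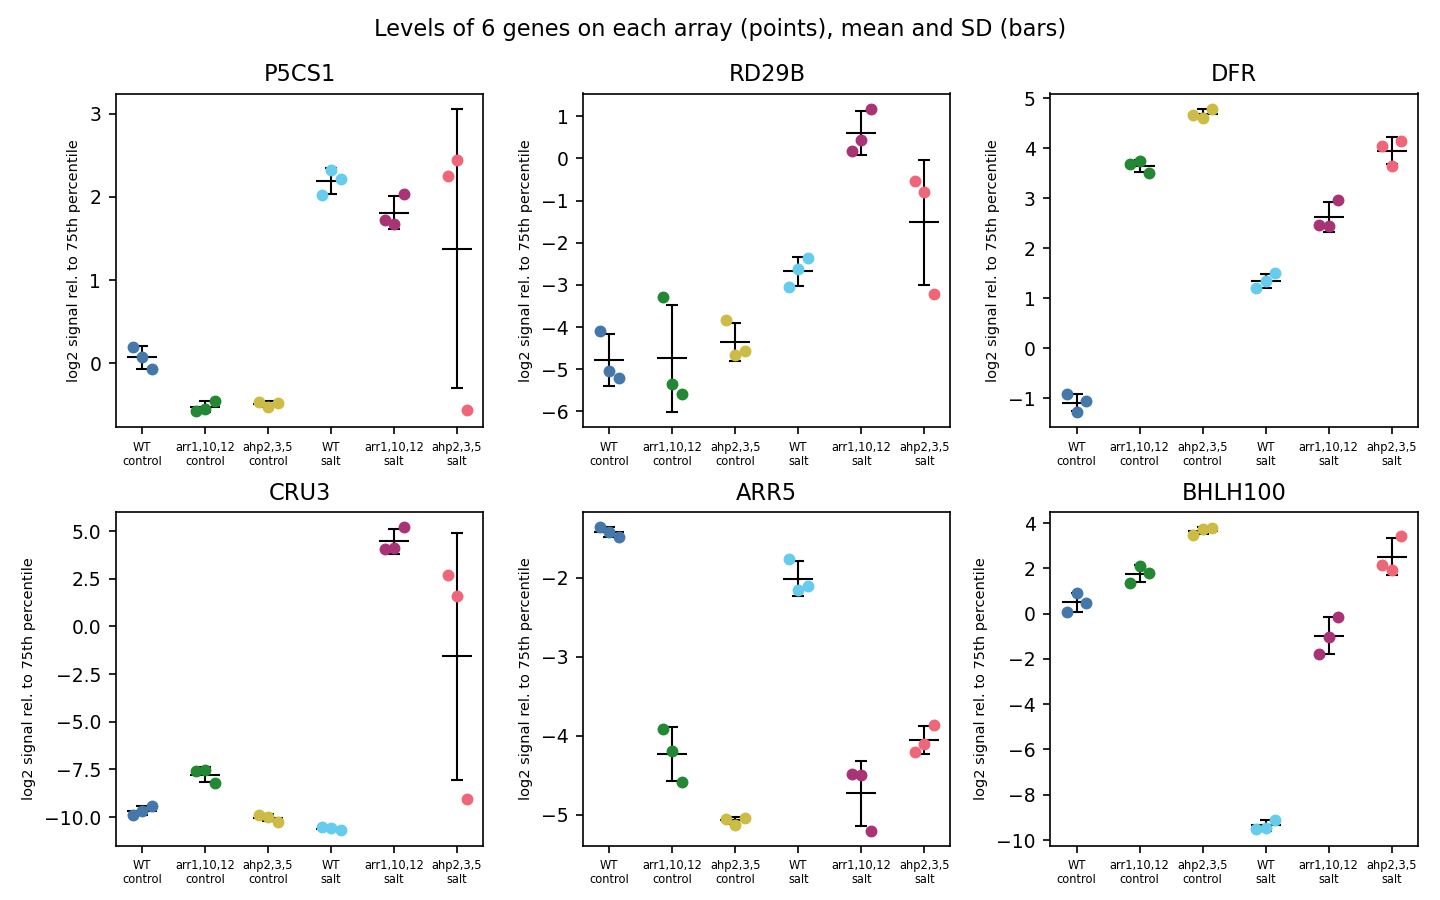
Log2 level of 6 genes on each array, relative to the 75th percentile of the array, by group, with each array as a point and the mean ± SD of the group beside the points. The genes were chosen after their values were seen, and DFR goes from -1.08 ± 0.18 in WT control to 4.69 ± 0.09 in ahp2,3,5 control.

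The salt response of the arr1,10,12 mutant was measured in the same way, to ask what changes under salt without these type-B regulators. Genes called higher included 7 of 7 seed, 22 of 31 abscisic acid response and 6 of 13 suberin genes, and those called lower 9 of 13 flavonol, 9 of 17 anthocyanin, 13 of 21 cell division and 11 of 23 root marker genes. Camera passed these lists at its preset correlation, and each had an adjusted p = 0.72 with an estimated correlation. The cruciferin gene CRA1 (AT5G44120), which encodes a seed storage protein, rose from -4.77 ± 1.37 to 4.85 ± 0.39 (788-fold, adjusted p = 8.6e-05), a cupin gene, AT2G28490, rose 556-fold, and the oleosin gene OLEO2 (AT5G40420) rose from -5.50 ± 1.25 to 2.36 ± 0.58 (232-fold). Without arr1,10,12 control replicate 1 these 3 folds were 1350, 849 and 377. The defensin genes PDF1.2b (AT2G26020) and PDF1.2c (AT5G44430) fell 41.6-fold and 40.4-fold.

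Of 7 seed genes 7 rose, and the 2S albumin gene SESA2 (AT4G27150) rose 17.1-fold (adjusted p = 4e-06) while SESA1 (AT4G27140) was at least 53-fold higher. Another cruciferin gene, CRU3 (AT4G28520), was above background on 1 of the 3 control arrays. Abscisic acid response genes rose in 22 of 31 cases, with the LEA genes EM6 (AT2G40170), EM1 (AT3G51810, n = 2 salt arrays) and LEA4-5 up 116-fold, 84.3-fold and 79-fold, and RD29B (AT5G52300) going from -4.74 ± 1.27 to 0.60 ± 0.53 (40.6-fold, and 67.2-fold without arr1,10,12 control replicate 1). Of 13 suberin genes 6 rose, among them the fatty acyl reductase genes FAR1 (AT5G22500) and FAR4 (AT3G44540, log2 1.56 and 1.5) and the acyltransferase gene GPAT5 (AT3G11430, 1.32).

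Flavonol genes fell in 9 of 13 cases, with TT7 (AT5G07990) 4.25-fold lower and the chalcone synthase gene TT4 (AT5G13930) at log2 -1.37 (adjusted p = 2.3e-05). Anthocyanin genes fell in 9 of 17 cases, including 3AT2 (AT1G03495, 5.6-fold lower) and LDOX (AT4G22880, log2 -1.62). Among the 21 cell division genes 13 fell, with CDKB1;2 (AT2G38620) and CYCB1;2 at log2 -1.51 and -1.48. Auxin genes fell in 5 of 22 cases, with the early response genes IAA29 (AT4G32280) and IAA19 (AT3G15540) at -1.78 and -1.66. Salicylic acid defence genes fell in 7 of 16 cases, with NIMIN1 (AT1G02450), WRKY38 (AT5G22570) and PR5 (AT1G75040) at -3.15 (2 of the 3 salt arrays above background), -2.85 and -2.15. Without arr1,10,12 control replicate 1 NIMIN1 was at -2.26 and WRKY38 at -1.93, and without replicate 2 WRKY38 was at -3.57. Phosphate starvation markers fell in 6 of 12 cases and rose in 1, with PEPC1 (AT1G17710) 6.15-fold lower and RNS1 (AT2G02990) at log2 1.46. Of 18 aquaporin genes 2 fell, TIP2;3 (AT5G47450, 5.75-fold lower) and TIP2;2 (AT4G17340, log2 -1.45). Of 40 photosynthesis genes 1 fell, PRK at log2 -1.03. Root markers fell in 11 of 23 cases, CASP1 and EXPA18 (AT1G62980) by 1.66 and 1.60 on the log2 scale.

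These 12 lists passed camera, with adjusted p of 2.3e-09 for abscisic acid response, 2.8e-06 for cell division, 3.9e-05 for photosynthesis, 1e-04 for seed, 0.00011 for flavonol, 0.00087 for suberin, 0.0012 for auxin, 0.0018 for root markers, 0.002 for anthocyanin, 0.006 for aquaporins, 0.0091 for phosphate and 0.025 for salicylic acid. Camera with an estimated correlation passed none of them, at adjusted p = 0.72 for each. Adjusted over the list alone, 12 root markers fell and the other counts were the same. In total 3138 of 22948 genes were called, 1040 higher and 2098 lower. The arr1,10,12 control and salt arrays were scanned on different days, and with the scan day as a fixed block, chosen after the data were seen, 1106 genes were called, and with normexp and quantile normalization 1640. Only the ahp2,3,5 controls span both days, with 1 array on the second, so the block rests on that array and costs precision. Without the array labelled ahp2,3,5 salt replicate 3, which here enters the variance alone, the salicylic acid list had an adjusted p of 0.056.

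The salt response of the ahp2,3,5 mutant contains the array that lay among the mutant controls, so its group spreads are wide. Genes called higher included 19 of 31 abscisic acid response, 6 of 7 seed and 7 of 13 suberin genes, and those called lower 9 of 13 flavonol and 5 of 17 anthocyanin genes. The preset correlation of camera passed these lists, with adjusted p = 0.72 for each with an estimated correlation. CRA1 went from -5.82 ± 0.12 to 0.88 ± 3.97 (104-fold, adjusted p = 0.0014), and an oleosin gene, AT3G01570, rose 23.1-fold. Without replicate 3 of the salt group these folds were 508 and 69.6, without replicate 1 they were 42.2 and 12.2, and without replicate 2 they were 52.7 and 14.6. PDF1.2c and PDF1.3 (AT2G26010) fell 29.1-fold and 28.9-fold (adjusted p = 2.9e-06 for the latter), and PDF1.2b was at least 29.7-fold lower.

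Of 31 abscisic acid response genes 19 rose, EM6 11.2-fold (adjusted p = 0.0066) and LEA4-5 by 3.28 on the log2 scale. Seed genes rose in 6 of 7 cases, with the embryo regulator gene ABI3 (AT3G24650) 4.36-fold higher. CRU3 was above background on 0 of the 3 control and 2 of the 3 salt arrays. Suberin genes rose in 7 of 13 cases, with CYP86A1 (AT5G58860) 2.77-fold higher and GPAT5 at log2 1.28. Flavonol genes fell in 9 of 13 cases, with TT7 going from 3.56 ± 0.21 to 1.25 ± 1.03 (4.96-fold lower) and F3H (AT3G51240) at log2 -1.53 (adjusted p = 1.1e-05). Anthocyanin genes fell in 5 of 17 cases, 3AT2 3.54-fold. Glucosinolate genes fell in 8 of 22 cases, with CYP79F1 (AT1G16410) and MAM3 (AT5G23020) at -1.87 and -1.65, while the regulator gene MYB29 (AT5G07690) rose by 1.09. Salicylic acid genes fell in 6 of 16 cases, with WRKY38 and NIMIN1 at -2.75 and -2.55. Auxin genes fell in 3 of 22 cases, with IAA6 (AT1G52830) and IAA19 at -1.47 and -1.24. Of 18 aquaporin genes 2 fell, TIP2;2 (-1.76) and TIP1;1 (AT2G36830, -1.03). Of 21 cell division genes 1 fell, KN (AT1G08560, -1.01), and of 17 phenylpropanoid genes 1 fell, 4CL3 (AT1G65060, -1.52). CYCB1;2, not called, went from 0.46 ± 0.06 to -0.44 ± 0.71, a wide spread with replicate 3 included. In the photosynthesis list limma called 0 of 40, although 37 were lower at an unadjusted p under 0.05, with a median log2 of -0.37. PRK, for example, went from 4.47 ± 0.05 to 3.55 ± 0.48. The member counts and this median include replicate 3 of the salt group, so they may understate the response of the other 2 arrays. Without replicate 3 of the salt group EM6 was 29-fold higher, LEA4-5 was at log2 4.52, TT7 was 7.46-fold lower, and CYP79F1 and MAM3 were at -2.85 and -2.63. Without replicate 1 EM6 was 6.77-fold higher and LEA4-5 at log2 2.57, and CYP79F1 and MAM3 at -0.88 and -0.95 were not called (adjusted p = 0.15 and 0.13). Without replicate 2 EM6 was 7.16-fold higher.

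Camera passed these 12 lists, with adjusted p of 3.4e-09 for photosynthesis, 9.9e-07 for flavonol, 1.8e-06 for abscisic acid response, 0.00031 for cell division, 0.00044 for anthocyanin, 0.00062 for aquaporins, 0.0013 for suberin, 0.0068 for phenylpropanoid, 0.0079 for auxin, 0.0089 for salicylic acid, 0.012 for seed and 0.048 for glucosinolate. None passed with an estimated correlation, at adjusted p = 0.72 to 0.82. Adjusted over the list alone, 20 abscisic acid and 8 suberin genes rose and 9 glucosinolate genes fell, with the other counts the same. In total 1789 of 22959 genes were called, 843 higher and 946 lower. Without replicate 3 of the salt group 3427 were called, 1466 higher and 1961 lower, and without replicate 2 of that group 1134 were called. Without replicate 3 the phenylpropanoid list had an adjusted p of 0.066 and the salicylic acid list 0.056. With the scan day as a fixed block 1056 genes were called, with the compared groups alone 497, and with normexp and quantile normalization 888.

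**Figure D3:**
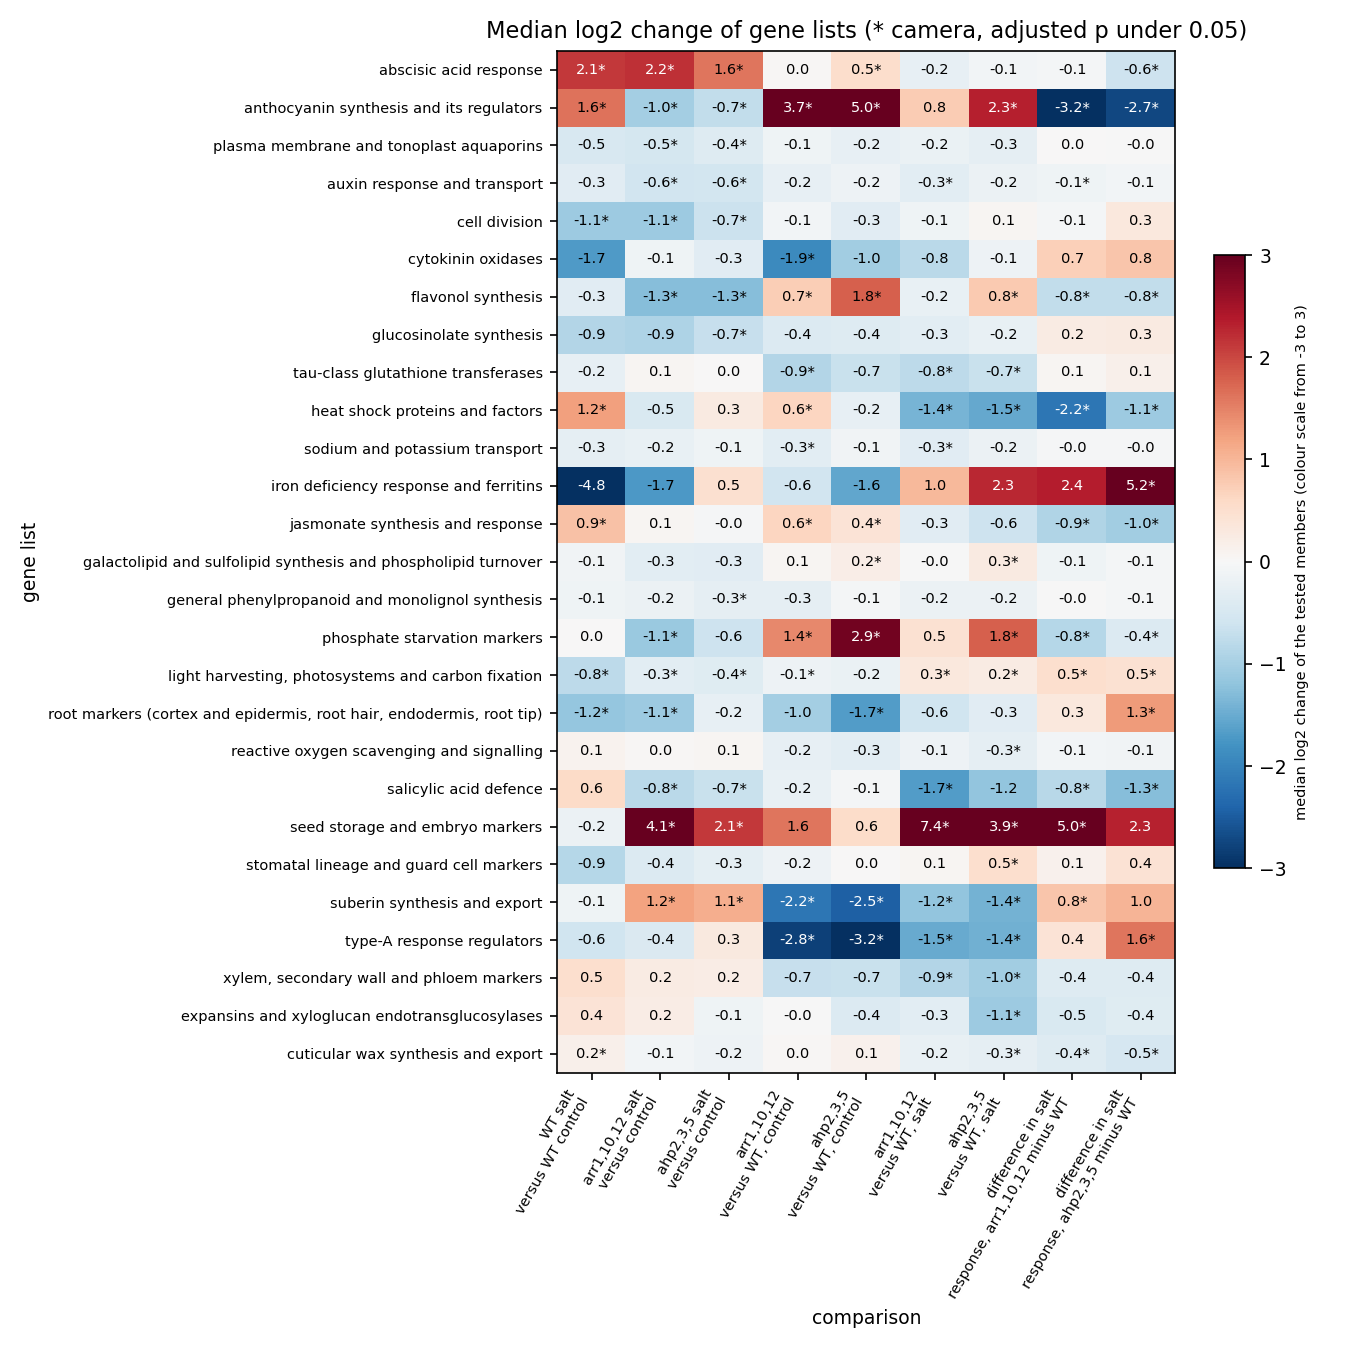
Median log2 change of the measured members of each gene list (rows) in each comparison (columns), with colour from -3 to 3 and an asterisk where camera gave an adjusted p under 0.05. The anthocyanin list has a median of 5.03 for ahp2,3,5 against WT without salt and 1.62 for the WT salt response.

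The arr1,10,12 mutant was compared with WT without salt to ask which transcripts depend on the type-B regulators in unstressed seedlings. Genes called lower included 6 of 9 type-A regulator, 4 of 7 cytokinin oxidase and 10 of 13 suberin genes, and those called higher 11 of 17 anthocyanin, 8 of 12 phosphate starvation and 8 of 27 jasmonate genes. Their lists passed camera at the preset correlation, with adjusted p = 0.72 for each with an estimated correlation. Apart from the targeted genes, the glucose 6-phosphate translocator gene GPT2 (AT1G61800) was 37.2-fold higher (adjusted p = 3e-07), and the terpene synthase gene TPS-CIN (AT3G25830) and the gene AT4G14060 were 108-fold and 110-fold lower (182-fold for TPS-CIN without arr1,10,12 control replicate 1). CYP82C2 was at least 113-fold lower.

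Of 9 type-A response regulators, which cytokinin induces and which dampen its signal, 6 were called lower and 0 higher. ARR15 (AT1G74890) went from -1.70 ± 0.08 in WT to -5.43 ± 0.21 in the mutant (13.3-fold lower, adjusted p = 1e-10), and ARR7 (AT1G19050) and ARR6 (AT5G62920) were 8.05-fold and 7.21-fold lower. Of 7 cytokinin oxidase genes 4 were lower, including CKX3 (AT5G56970, 6.26-fold) and CKX5 (AT1G75450, log2 -1.94). Anthocyanin genes were higher in 11 of 17 cases, with DFR going from -1.08 ± 0.18 to 3.65 ± 0.13 (26.5-fold, adjusted p = 1.1e-10) and the bHLH regulator gene TT8 (AT4G09820) 19.9-fold higher. Flavonol genes were higher in 2 of 13 cases, MYB11 (AT3G62610, log2 2.32) and TT7 (2.29), and lower in 1, MYB12 (AT2G47460, -1.37). Jasmonate genes were higher in 8 of 27 cases, with PDF1.2c 22.5-fold and CORI3 9.9-fold higher. Phosphate starvation markers were higher in 8 of 12 cases, with the phosphatase gene PS2 (AT1G73010) 10.4-fold higher and SPX1 (AT5G20150) at log2 1.84, and lower in 2, among them the phosphate transporter gene PHT1;2 (AT5G43370, -1.93).

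Suberin genes were lower in 10 of 13 cases, with FAR5 (AT3G44550) 8.67-fold and CYP86A1 6.25-fold lower. Root markers, of which 10 of 23 were lower with a median log2 of -1.02, moved with them, though that list missed the threshold (camera adjusted p = 0.066). Tau-class glutathione transferase genes were lower in 9 of 21 cases, with GSTU22 (AT1G78340) and GSTU10 (AT1G74590) at -2.50 and -2.43. Of 19 sodium and potassium transport genes 2 were lower, the exchanger gene CHX17 (AT4G23700, -2.03) and the sodium transporter gene HKT1 (AT4G10310, -1.84). Of 15 heat shock genes 1 was called higher, HSP22 (AT4G10250), at -7.60 ± 0.19 in WT, where 2 of the 3 arrays were above background, and -5.25 ± 1.93 in the mutant (log2 2.36, and 1.24 without arr1,10,12 control replicate 2). Of the photosynthesis genes limma called 0 of 40, with 16 lower at an unadjusted p under 0.05.

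Camera passed these 11 lists, with adjusted p of 4.3e-10 for anthocyanin, 1.3e-06 for type-A regulators, 2.2e-05 for jasmonate, 2.8e-05 for suberin, 8.6e-05 for phosphate, 0.0033 for flavonol, 0.0098 for glutathione transferases, 0.025 for cytokinin oxidases, 0.031 for heat shock, 0.032 for photosynthesis and 0.033 for ion transport. With an estimated correlation none passed, at adjusted p = 0.72 to 0.83. Adjusted over the list alone, 12 anthocyanin genes were higher and the other counts were the same. In total 2896 of 22837 genes were called, 853 higher and 2043 lower. Within the slide that held all 3 WT control arrays and 1 arr1,10,12 control array 2221 genes were called, 2058 of them among the 2896, but these share arrays with the main comparison, and the lone mutant array is assumed to vary like the other groups. The medians of the 11 lists were there -2.44 for type-A regulators, -1.61 for cytokinin oxidases, 3.66 for anthocyanin, 0.71 for flavonol, 1.09 for jasmonate, 1.01 for phosphate, -2.14 for suberin, -0.53 for glutathione transferases, -0.31 for ion transport, -0.1 for photosynthesis and 0.11 for heat shock (0.64 over all arrays), with -1.03 for root markers. With normexp and quantile normalization 1675 genes were called. Without the array labelled ahp2,3,5 salt replicate 3 the photosynthesis list had an adjusted p of 0.054.

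The ahp2,3,5 mutant was compared with WT without salt to ask which transcripts depend on the phosphotransfer proteins. Genes called lower included 8 of 9 type-A regulator, 11 of 13 suberin and 18 of 23 root marker genes, and those called higher 12 of 17 anthocyanin, 9 of 13 flavonol and 10 of 12 phosphate starvation genes. At the preset correlation camera passed these lists, with adjusted p = 0.72 for each with an estimated correlation. GPT2 was 188-fold higher (adjusted p = 5.7e-09), the acyltransferase gene 3AT2 61.6-fold and TT8 56.9-fold. The genes AIR1 (AT4G12550) and GLP9 (AT4G14630) were 138-fold and 126-fold lower, and CYP82C2 was at least 116-fold lower.

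Type-A regulators were lower in 8 of 9 cases, with ARR7 29.9-fold and ARR6 21.6-fold lower and ARR5 (AT3G48100) going from -1.42 ± 0.06 to -5.07 ± 0.05 (12.6-fold lower, adjusted p = 5.7e-09). Cytokinin oxidase genes were lower in 4 of 7 cases, with CKX4 (AT4G29740), CKX2 (AT2G19500), CKX5 and CKX3 at log2 -2.79, -1.98, -1.52 and -1.04, but the list missed the threshold (camera adjusted p = 0.26). Anthocyanin genes were higher in 12 of 17 cases, with DFR at 4.69 ± 0.09 in the mutant (54.7-fold, adjusted p = 1.3e-11). Flavonol genes were higher in 9 of 13 cases, with TT7 19.7-fold higher and F3H at log2 2.09. Of 12 phosphate starvation markers 10 were higher, including PS2 (22.8-fold) and PEPC1 (12.5-fold), and 2 were lower, among them PHT1;2 (log2 -2.37). Of 18 lipid remodelling genes 7 were higher, with the galactolipid synthase gene MGD3 (AT2G11810) 14.6-fold and the phosphodiesterase gene GDPD1 (AT3G02040) 8.78-fold higher, and 2 were lower, among them NPC4 (AT3G03530, -1.74). Jasmonate genes were higher in 9 of 27 cases, with CORI3 11.7-fold higher. Abscisic acid response genes were higher in 5 of 31 cases, with TSPO 13.9-fold higher, and lower in 5, with COR15B (AT2G42530) at log2 -1.90.

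Suberin genes were lower in 11 of 13 cases, with FAR5 13.4-fold and CYP86A1 8.58-fold lower. Root markers moved with them: 18 of 23 were lower, with the NADPH oxidase gene of root hair growth RHD2 (AT5G51060) 10.9-fold lower and EXPA18 at log2 -3.03 (-3.62 and -2.35 without ahp2,3,5 control replicates 1 and 2). Camera passed 9 lists, with adjusted p of 1.3e-10 for anthocyanin, 2.5e-07 for flavonol, 5.2e-06 for phosphate and for type-A regulators, 0.00015 for suberin, 8e-04 for jasmonate, 0.0016 for root markers, 0.0062 for abscisic acid response and 0.0079 for lipid remodelling. Camera with an estimated correlation passed none of them, at adjusted p = 0.72 to 0.77. Adjusted over the list alone, 8 jasmonate genes were higher and the other counts were the same. In total 3807 of 22841 genes were called, 1126 higher and 2681 lower. With the slide as a fixed block 2445 were called, and with normexp and quantile normalization 2294.

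Under salt the arr1,10,12 mutant was compared with WT. Genes called higher in the mutant included 6 of 7 seed genes, and those called lower 5 of 9 type-A regulator, 9 of 16 salicylic acid defence, 8 of 15 heat shock, 7 of 13 suberin and 6 of 13 vascular genes. These lists passed at the preset correlation of camera, with adjusted p = 0.72 to 0.73 with an estimated correlation. CRU3 was at least 8060-fold higher, at 4.47 ± 0.64 against an undetected -10.61 ± 0.09 (adjusted p = 4.1e-05). CRA1 was 621-fold higher (from -4.43 ± 0.25 to 4.85 ± 0.39) and the oleosin gene OLEO1 (AT4G25140) 463-fold. AT4G14060 was 292-fold lower and the syntaxin gene SYP124 (AT1G61290) had a log2 difference of -5.32.

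Seed genes were higher in 6 of 7 cases, including SESA2 (at least 219-fold), and lower in 1, the regulator gene FUS3 (AT3G26790, log2 -1.65). Type-A regulators were lower in 5 of 9 cases, with ARR7 10.5-fold lower (adjusted p = 2.4e-08) and ARR5 at log2 -2.72. Of 7 cytokinin oxidases 2 were lower, CKX3 (-1.86) and CKX4 (-1.19), while CKX6 (AT3G63440) and CKX1 (AT2G41510) at -0.88 and -0.80 were not called (adjusted p = 0.091 and 0.17). Salicylic acid defence genes were lower in 9 of 16 cases, with WRKY38 28.9-fold and the monooxygenase gene FMO1 (AT1G19250) 16.3-fold lower. Heat shock genes were lower in 8 of 15 cases, with HSP22 10.7-fold and HSFA2 5.22-fold lower. Tau-class glutathione transferases were lower in 7 of 21 cases, with GSTU9 (AT5G62480) and GSTU22 at -2.63 and -2.55. Auxin genes were lower in 6 of 22 cases, with the auxin conjugation gene GH3.3 (AT2G23170) 8.3-fold lower. Suberin genes were lower in 7 of 13 cases, with CYP86B1 (AT5G23190) at -1.28. Root markers, lower in 7 of 23 cases with a median log2 of -0.59, did not pass as a list (camera adjusted p = 0.16). Xylem, secondary wall and phloem genes were lower in 6 of 13 cases, with the cellulose synthase genes CESA7 (AT5G17420) and CESA4 (AT5G44030) at -1.21 and -1.20, and higher in 1, the phloem regulator gene APL (AT1G79430, 1.16). In the ion transport list 2 of 19 were lower, HKT1 (-1.29, 2 of the 3 mutant arrays above background) and NHX4 (AT3G06370, -1.07), and 1 was higher, NHX3 (AT5G55470, 1.51). In the photosynthesis list limma called 0 of 40, with 31 higher at an unadjusted p under 0.05 and a median log2 of 0.32.

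Camera passed 10 of these lists, with adjusted p of 1.6e-06 for photosynthesis, 5e-05 for type-A regulators, 8e-04 for seed, 0.0037 for salicylic acid, 0.0075 for glutathione transferases, 0.011 for suberin, 0.023 for auxin, 0.024 for ion transport, 0.028 for heat shock and 0.048 for vascular genes. None passed with an estimated correlation, at adjusted p = 0.72 to 0.73. The counts of these 10 lists adjusted over the list alone were the same. In total 3322 of 22956 genes were called, 1098 higher and 2224 lower, and with normexp and quantile normalization 1741.

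Under salt the ahp2,3,5 mutant was compared with WT, and some genes of iron-deficiency transcription factors were far higher in the mutant. No slide held salt arrays of both genotypes, so here too a slide effect cannot be told apart from the genotype. BHLH100 was at least 2080-fold higher, at 2.52 ± 0.81 against an undetected -9.36 ± 0.22 (adjusted p = 2.7e-10), and BHLH38, BHLH101 and BHLH39 (AT3G56980) were 1310-fold, 431-fold and 91.4-fold higher (787-fold for BHLH38 and 53.4-fold for BHLH39 without ahp2,3,5 salt replicate 3). Also called higher were 11 of 17 anthocyanin, 8 of 12 phosphate starvation and 5 of 7 seed genes, and called lower 5 of 9 type-A regulator, 11 of 13 suberin and 8 of 13 vascular genes. These lists passed camera, with adjusted p = 0.72 for each with an estimated correlation. Of the 10 iron deficiency and ferritin genes 5 were higher and 3 lower, and the list as a whole missed the threshold (camera adjusted p = 0.14). Since the list also holds ferritins, this is not a test of the deficiency genes alone. The means of BHLH100, BHLH38, BHLH101 and BHLH39 were also above WT in arr1,10,12 with salt, at -0.99, -0.99, -1.06 and -1.93. In WT with salt they were at -9.36, -7.89, -6.89 and -5.02. Without salt they were at 3.67, 4.05, 3.31 and 3.21 in ahp2,3,5 and 1.76, 2.88, 1.7 and 1.96 in arr1,10,12. In WT control they were at 0.49, 0.25, 0.31 and -0.23. In ahp2,3,5 with salt AT4G14060 was 268-fold lower than in WT and AT5G47050 191-fold lower.

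Anthocyanin genes were higher in 11 of 17 cases, with 3AT2 8.4-fold higher and 3AT1 (AT1G03940) at log2 3.02. Flavonol genes were higher in 5 of 13 cases, with TT7 and CHIL (AT5G05270) at log2 1.88 and 1.79. Phosphate starvation markers were higher in 8 of 12 cases, with PEPC1 12.8-fold and the non-coding RNA gene AT4 (AT5G03545) 10.1-fold higher, and lower in 3, among them PHT1;2 (-1.51). Lipid remodelling genes were higher in 7 of 18 cases, with MGD3 10.7-fold higher and the sulfolipid synthase gene SQD2 (AT5G01220) at log2 1.62, and lower in 1, NPC4 (-1.01). Seed genes were higher in 5 of 7 cases, including CRA1 (39.8-fold) and SESA2 (at least 42.4-fold). Type-A regulators were lower in 5 of 9 cases, with ARR7 5.7-fold lower and ARR5 at log2 -2.05, while ARR3 (AT1G59940) at -1.60, above background on 2 of the 3 mutant arrays, was not called (adjusted p = 0.18). Among the cytokinin oxidases CKX3 was lower (-1.32), CKX4 at -0.60 was not called (adjusted p = 0.24) and CKX7 (AT5G21482) at -0.46 was under 2-fold (adjusted p = 0.0075). Without ahp2,3,5 salt replicate 3 CRA1 was 194-fold higher, TT7 was at log2 1.29, and ARR3 (-2.91, adjusted p = 0.005) and CKX4 (-1.3, adjusted p = 0.00017) were called lower. Without replicates 1 and 2 of that group CRA1 was 16.2-fold and 20.1-fold higher, and without replicate 1 ARR3 was at -0.08 (adjusted p = 0.92).

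Suberin genes were lower in 11 of 13 cases, with GPAT7 (AT5G06090) and CYP86B1 at log2 -1.91 and -1.66. Root markers, lower in 5 of 23 cases with a median log2 of -0.33, did not pass as a list (camera adjusted p = 0.33). Vascular genes were lower in 8 of 13 cases, with the protease gene XCP1 (AT4G35350) at -1.99 (n = 2 WT arrays). Expansin and xyloglucan endotransglucosylase genes were lower in 10 of 21 cases, with XTH23 (AT4G25810) 7.22-fold lower, and higher in 2, among them XTH31 (AT3G44990, 1.33). Wax genes were lower in 5 of 20 cases, with WSD1 11.5-fold lower and CER1 at -2.12. Heat shock genes were lower in 7 of 15 cases, HSFA2 7.12-fold. Reactive oxygen genes were lower in 5 of 20 cases, with the kinase gene OXI1 (AT3G25250) 7.7-fold lower and ZAT12 (AT5G59820) at -2.80. Tau-class glutathione transferases were lower in 7 of 21 cases, with GSTU2 (AT2G29480) and GSTU25 (AT1G17180) at -2.10 and -1.95. In the photosynthesis list limma called 0 of 40 (29 higher at an unadjusted p under 0.05) and in the stomatal list 0 of 10 (8 higher at an unadjusted p under 0.05). Without ahp2,3,5 salt replicate 3 HSFA2 was 4.32-fold lower and CER1 was at -1.41.

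Camera passed 15 lists, with adjusted p of 5.2e-06 for anthocyanin, 0.00019 for photosynthesis and for type-A regulators, 6e-04 for suberin, 0.0032 for phosphate, 0.0056 for glutathione transferases, 0.0084 for wall loosening, 0.0095 for vascular genes, 0.013 for seed and for stomata, 0.016 for lipid remodelling, 0.023 for wax, 0.029 for heat shock, 0.041 for flavonol and 0.044 for reactive oxygen. With an estimated correlation none passed, at adjusted p = 0.72 to 0.77. The counts of these 15 lists adjusted over the list alone were the same. In total 3239 of 22962 genes were called, 1267 higher and 1972 lower, and with normexp and quantile normalization 1765. Without the array labelled ahp2,3,5 salt replicate 3 the heat shock, flavonol and reactive oxygen lists had adjusted p of 0.097, 0.23 and 0.14.

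The difference between the salt responses of arr1,10,12 and WT tests which responses differ in the mutant, whether through the control or the salt level. The salt arrays of WT and of the mutant were on different slides, so a slide effect on the salt level cannot be told apart from the genotype. Genes called with a less positive response in the mutant included 11 of 17 anthocyanin and 8 of 15 heat shock genes, and those with a more positive one 6 of 7 seed and 6 of 13 suberin genes. Camera at the preset correlation passed these lists, with adjusted p = 0.72 to 0.75 with an estimated correlation. CRA1 had a 206-fold higher response in the mutant (352-fold without arr1,10,12 control replicate 1), and GPT2 had a 35-fold lower one. GPT2 went from -3.61 ± 0.53 to 1.62 ± 0.67 in WT and from 1.61 ± 0.23 to 1.70 ± 0.38 in the mutant, so its control level differed. CORI3 and DFR, listed below, were also higher in the mutant control (2.96 and 3.65 against -0.35 and -1.08 in WT). With salt they were at 3.07 and 2.63 in the mutant and at 3.27 and 1.35 in WT. WRKY38 went from -5.59 ± 0.31 to -1.69 ± 0.33 in WT and the other way in the mutant, from -3.70 ± 1.67 to -6.55 ± 0.47, a 108-fold lower response (56.9-fold and 177-fold without arr1,10,12 control replicates 1 and 2). GH3.3 went from -0.43 ± 0.11 to 3.00 ± 0.06 in WT and from 1.16 ± 0.08 to -0.05 ± 0.37 in the mutant, a 25-fold lower response (adjusted p = 3.8e-07). Of 17 anthocyanin genes 11 had a lower response, including 5MAT (AT3G29590, 12.1-fold) and DFR (10.9-fold, adjusted p = 3.8e-07). Of 15 heat shock genes 8 had a lower response, HSFA2 8.15-fold. Of 27 jasmonate genes 3 did, CORI3 11.3-fold. Of 13 flavonol genes 4 did, with MYB11 at a log2 difference of -2.31, and of 12 phosphate markers 5 did, with RNS1 at -3.35. Of 16 salicylic acid genes 5 did, with the regulator gene SARD1 (AT1G73805) at -4.47, and of 22 auxin genes 6 did, with IAA3 (AT1G04240) at -1.30. Seed genes had a higher response in 6 of 7 cases and suberin genes in 6 of 13, with FAR5 and FAR4 at 1.95 and 1.72, whereas limma called 0 of 23 root markers, with 1 higher at an unadjusted p under 0.05 (median 0.31, camera adjusted p = 0.78). In the photosynthesis list 1 of 40 had a higher response, LHCB4.2 (1.00), and in the wax list limma called 0 of 20, with 9 lower at an unadjusted p under 0.05. Among cytokinin genes the responses of ARR15 (1.46, adjusted p = 5.9e-05), CKX2 (1.93) and CKX5 (1.42) were higher, and those of ARR6 (0.66, adjusted p = 0.065) and CKX3 (0.79, adjusted p = 0.2) were not called.

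Camera passed 11 lists, with adjusted p of 1e-09 for photosynthesis, 1.5e-09 for anthocyanin, 2.8e-06 for jasmonate, 3.1e-05 for heat shock, 6.9e-05 for flavonol, 0.00013 for wax, 2e-04 for phosphate, 0.0024 for seed, 0.0033 for salicylic acid, 0.019 for auxin and 0.023 for suberin. Camera with an estimated correlation passed none of them, at adjusted p = 0.72 to 0.75. Adjusted over the list alone, 10 heat shock genes and 6 salicylic acid genes had a lower response, 1 salicylic acid gene a higher one, and the other counts were the same. In total 1848 of 22831 genes were called, 989 with a higher and 859 with a lower response in the mutant. With the deposited matrix values the balance turned, with 863 higher and 954 lower.

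The same difference for ahp2,3,5 again held the array labelled ahp2,3,5 salt replicate 3, and its salt arrays were on other slides than those of WT. Genes called with a more positive response than in WT included 6 of 10 iron deficiency or ferritin genes and 5 of 9 type-A regulator genes. Those with a less positive one included 11 of 17 anthocyanin and 9 of 27 jasmonate genes. These 4 lists passed camera, with adjusted p = 0.72 for each with an estimated correlation. The root iron transporter gene IRT1 (AT4G19690) was at 0.01 ± 0.81 in WT control, -5.21 ± 0.73 in WT salt, -5.14 ± 0.84 in ahp2,3,5 control and -2.31 ± 0.41 in ahp2,3,5 salt, a 266-fold difference in response (adjusted p = 0.00083). BHLH38, at 0.25 ± 0.56, -7.89 ± 0.38, 4.05 ± 0.12 and 2.47 ± 1.34 in the same groups, differed 93.3-fold, and the ferric reductase gene FRO2 (AT1G01580) 36.5-fold. Of 10 iron deficiency and ferritin genes 6 had a higher response and 0 a lower one. Of 9 type-A regulators 5 had a higher response, with ARR6 6.52-fold higher (adjusted p = 4.5e-06) and ARR7, ARR15 and ARR4 (AT1G10470) at 2.39, 2.2 and 1.84. Among the cytokinin oxidases CKX4, CKX2 and CKX5 were higher (2.19, 1.83 and 1.42) and CKX7 at -0.86 was under 2-fold (adjusted p = 0.0023). Root markers, of which 9 of 23 had a higher response, moved with the iron genes, with RHD2 and RCI3 at 2.13 and 2.04. Without ahp2,3,5 salt replicate 3 the differences were 56.1-fold for BHLH38, 22.3-fold for FRO2 and 1.49 on the log2 scale for CKX4.

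A lower response was called for 11 of 17 anthocyanin genes (PAP1 9.93-fold, adjusted p = 1.1e-06), 9 of 27 jasmonate genes (CORI3 12.1-fold), 5 of 13 flavonol genes (TT7, log2 -2.42), 4 of 15 heat shock genes (HSFA2 12.9-fold), 5 of 31 abscisic acid response genes (TSPO -3.64, LEA7 -2.93), 3 of 12 phosphate markers (RNS1 -4.12) and 2 of 20 wax genes (WSD1 -1.61). Of 16 salicylic acid genes 7 had a lower response, SARD1 at -4.32, and 1 a higher one, WRKY54 (AT2G40750) at 1.5. In the photosynthesis list 3 of 40 had a higher response, among them LHCB4.2 (1.04). Here too a lower response could come with a higher control level. PAP1 and CORI3 were at 3.00 and 3.21 in ahp2,3,5 control against -1.96 and -0.35 in WT control. With salt they were at 2.45 and 3.22 against 0.79 and 3.27. Without ahp2,3,5 salt replicate 3 the difference for HSFA2 was 7.84-fold, and those for TT7, TSPO, LEA7 and RNS1 were -3.01, -2.88, -1.99 and -3.49 on the log2 scale, and without WT control replicate 1 that for LEA7 was -3.54. Camera passed 12 lists, with adjusted p of 3.8e-08 for anthocyanin, 1.3e-06 for jasmonate, 5.2e-06 for photosynthesis, 9e-06 for wax, 2.7e-05 for flavonol, 0.00035 for type-A regulators, 0.001 for abscisic acid response, 0.0084 for heat shock, 0.011 for salicylic acid, 0.014 for iron and for root markers and 0.029 for phosphate. None passed with an estimated correlation, at adjusted p = 0.72 to 0.77. Adjusted over the list alone, 7 iron and 13 root genes had a higher response, 10 jasmonate and 3 wax genes a lower one, and the other counts were the same. In total 2825 of 22836 genes were called, 1741 with a higher and 1084 with a lower response. Without the array labelled ahp2,3,5 salt replicate 3 the abscisic acid response and root marker lists each had an adjusted p of 0.11.

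The effects of the mutants were compared with each other across 22561 genes, which are not independent replicates. Without salt 651 genes were higher in both mutants (42 if the calls were independent), 1827 were lower in both (241) and 3 were called in opposite directions, with r = 0.888 across genes. With salt 771 were higher in both (60), 1517 lower in both (192) and 1 opposite, with r = 0.85. Both mutants share the WT arrays. In simulations where neither mutant had any effect, r was 0.361 without salt and 0.168 with salt. Such an r between values that hold noise alone is no baseline for r between real effects. The covariance across genes was 0.742 without salt and 0.745 with salt, against 0.011 and 0.009 in the simulations. With salt no mutant salt array was on the slide of the WT salt arrays, and the simulations do not cover a slide effect. Of the salt responses, arr1,10,12 and WT shared 633 genes called higher and 1471 lower, with 58 opposite and r = 0.664. The ahp2,3,5 mutant and WT shared 416 higher and 583 lower, with 91 opposite and r = 0.518. The ahp2,3,5 values with salt include the array labelled ahp2,3,5 salt replicate 3. Without it limma called 3427 in place of 1789 genes for that salt response. The lower overlap and r can therefore not be put down to the genotype.

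Directly compared without salt, ahp2,3,5 and arr1,10,12 differed in targeted genes, with ARR12, ARR10 and ARR1 at log2 differences of 6.86, 5.33 and 3.71 and AHP3 and AHP2 at -6.31 and -3.68. The anthocyanin activator gene PAP2 was 13-fold higher in ahp2,3,5 and the boron transporter gene BOR5 (AT1G74810) 10-fold higher, while NAS2 (AT5G56080), a nicotianamine synthase gene, had a log2 difference of -3.61 and ABI4 (AT2G40220) was at least 4.3-fold lower. Under salt, besides the targeted genes (ARR10 5.90, ARR1 4.28, AHP3 -6.71), the iron-deficiency genes BHLH100, BHLH38 and BHLH39 were 11.3-fold, 11-fold and 10.7-fold higher in ahp2,3,5 and MGD3 was 10.5-fold higher. The oleosin gene OLEO1 was 24.5-fold lower (adjusted p = 0.034) and AT5G47050 333-fold lower. Without ahp2,3,5 salt replicate 3 OLEO1 was 4.47-fold lower, and BHLH38 and BHLH39 were 6.59-fold and 6.23-fold higher. Without replicates 1 and 2 of that group OLEO1 was 66.7-fold and 49.5-fold lower, and without arr1,10,12 salt replicate 3 BHLH38 was 16.8-fold higher. In total 608 of 22952 genes were called without salt, 274 higher and 334 lower in ahp2,3,5, and 693 of 22955 with salt, 362 higher and 331 lower. With normexp and quantile normalization 316 and 369 genes were called, and the share called higher was 56.6% in place of 45.1% without salt and 39.3% in place of 52.2% with salt. Within the slide that held 2 arrays of each mutant control 397 genes were called, 347 of them shared with the 608, which rest partly on the same arrays. Within the slide that held all arr1,10,12 salt arrays and 1 ahp2,3,5 salt array 233 were called, 155 of them shared with the 693, with the lone array assumed to vary like the other groups. With the compared groups alone 14 genes were called with salt, and without replicate 1 or replicate 2 of the ahp2,3,5 salt group 1294 or 1047 genes were called.

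Over all 36 lists and 9 comparisons 100 of 324 list results passed camera with the preset correlation of 0.01, and 0 passed with an estimated correlation, where 19 had an unadjusted p under 0.05. Fry, which asks whether the genes of a list move one way without comparing them with other genes, passed 189. Some lists passed in no comparison, and their lowest adjusted p was 0.099 for abscisic acid synthesis and breakdown (WT salt response, 4 of 12 rose) and 0.097 for cytokinin receptors and the other relay genes (ahp2,3,5 against WT with salt, 1 of 9 higher and 1 lower). For cytokinin synthesis and activation it was 0.16 (arr1,10,12 salt response, 1 of 16 rose and 6 fell) and for plastid fatty acid synthesis 0.37 (the same response, 2 of 20 fell). For nitrate uptake and reduction it was 0.18 (ahp2,3,5 against WT with salt, 3 of 8 lower) and for proline and galactinol-raffinose metabolism 0.2 (arr1,10,12 against WT with salt, 3 of 14 lower). For senescence and chlorophyll breakdown it was 0.23 (WT salt response, 1 of 17 fell) and for triacylglycerol synthesis 0.092 (ahp2,3,5 against WT without salt, 3 of 15 higher). For commonly used reference genes it was 0.14 (ahp2,3,5 salt response), where limma called 0 of 10 and 3 were lower at an unadjusted p under 0.05.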

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

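The tests of the 3 patterns below were chosen after the results were seen, and the 11 counts of other splits of the arrays were planned before. The salt response differed between arr1,10,12 and WT in 1848 genes and between ahp2,3,5 and WT in 2825 genes, by the test of the difference itself. The second count includes the array labelled ahp2,3,5 salt replicate 3, and part of it may come from that array. Leaving out 1 array at a time gave 2417 to 3581 genes for it. In both counts the salt arrays of WT and of the mutant were on different slides. Probes without a locus code, which the gene comparisons do not use, also responded to salt, with 583 of 2431 tested probes called in WT, 331 in arr1,10,12 and 170 in ahp2,3,5.

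The array labelled ahp2,3,5 salt replicate 3 lay nearer to the controls of both mutants (SD of the log2 difference 0.523 from arr1,10,12 and 0.526 from ahp2,3,5) than to the other 2 arrays of its group (0.881). A swap with another genotype is argued against by AHP2, AHP3 and AHP5, which differed from the ahp2,3,5 control mean by at most 0.91 and lay at -3.63, -6.29 and -3.59 relative to WT. A dim hybridization is argued against by 77.3% of probes well above background, against 74.5% to 77.9% on the other arrays. Over 300 genes that rose most and 300 that fell most on the other 2 arrays, it showed a median share of 0.15 of their log2 change (quartiles -0.01 and 0.33). A wrong label or a missing salt exposure of an ahp2,3,5 sample would give such a low share. BHLH100 followed this, at 3.44 near the ahp2,3,5 controls (3.49 to 3.77) and above the other 2 salt arrays (2.17 and 1.93). P5CS1 (AT2G39800), CRU3 and RD29B also lay nearer the ahp2,3,5 controls, at -0.56, -9.04 and -3.22. The controls were at -0.53 to -0.47, -10.24 to -9.88 and -4.66 to -3.83. The other 2 salt arrays were at 2.25 and 2.45, 2.70 and 1.62, and -0.53 and -0.79. ARR5 did not follow this, at -3.86 with those salt arrays (-4.20 and -4.11) and above the controls (-5.13 to -5.04). DFR, at 4.15, was also with those salt arrays (4.05 and 3.64) and below the controls (4.61 to 4.79). The array also lay further from the ahp2,3,5 controls than each of these from the others (0.269 to 0.321), so neither account is settled. A mixture with a small share of salt-treated RNA stays open, since the median share on the linear scale was 0.047 and its quartiles of 0.004 and 0.176 lie on both sides of the bound of 0.05, and a biological difference of this sample was not tested.

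The salt response of WT and arr1,10,12 almost coincides with the scan day, since each of their salt arrays was scanned on the second day and each of their control arrays on the first. The ahp2,3,5 control array scanned on the second day, on the slide of the WT salt arrays, argues against the scan day, or for WT the slide, as the whole cause. Its difference from the other 2 ahp2,3,5 controls had a slope of 0.002 on the WT salt response over 22696 genes and -0.021 on that of arr1,10,12. This is 1 array, and it cannot speak to the slide of the arr1,10,12 salt arrays, which held no control array. The array labelled ahp2,3,5 salt replicate 3, scanned on the second day on another slide, had slopes of -0.066 and 0.042. A smaller contribution to single genes cannot be measured beyond these arrays, and an effect of the salt treatment itself remains a hypothesis that may account for the pattern.

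The seed storage transcripts CRA1 and CRU3 were high on the 5 salt arrays of the mutants other than ahp2,3,5 salt replicate 3, while SESA2 was at -3.21 on that array, at a mean of -3.05 on the other 2 of its group, and already at -4.83 and -4.12 in the arr1,10,12 and ahp2,3,5 controls (an undetected -8.80 in WT). Seeds or seed coats among the collected seedlings could explain part of the pattern and stay open, since 5 of 7 storage protein genes were above background on all 5 arrays and SESA3 and SESA4 on 1 of 5. Carry-over on 1 slide stays open for the genes as a set: on ahp2,3,5 salt replicate 2, on another slide, the 5 genes above background on the first slide lay a median of 4.65 log2 units above the ahp2,3,5 controls (quartiles 1.18 and 8.68), and all 7 a median of 1.18. For CRA1 and CRU3 alone, at 8.68 and 11.65 units, that array argues against it. An induction of these genes by salt in the mutants stays open too and was not tested.

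Other splits of the same arrays were counted for each comparison. For the difference in salt response of arr1,10,12, 9 of 100 exchanges of the genotype labels within a condition gave at least the 1848 genes called, so chance cannot be excluded by this count, and the highest was 5753. For ahp2,3,5, 4 of 100 did, a share under 0.05, with 2825 for the real labels and 3860 as the highest other. The 8 and 3 other exchanges with as many genes each moved a net 2 or 3 arrays between genotypes in 1 condition, which puts the genotype difference into the contrast and points to that structure. Among the exchanges that moved fewer, the highest counts were 932 over 90 exchanges and 2575 over 91. For the other 9 comparisons the 10 splits are too few for a share under 0.05, and in each 1 of the 10, the real one, gave as many genes. The real counts and the highest other counts were 4992 and 0 for WT salt, 3138 and 0 for arr1,10,12 salt, and 1789 and 1183 for ahp2,3,5 salt, where that other split put ahp2,3,5 salt replicate 3 with 2 control arrays. They were 2896 and 1 for arr1,10,12 against WT without salt, 3807 and 2 for ahp2,3,5, 3322 and 0 for arr1,10,12 with salt and 3239 and 1 for ahp2,3,5. Between the mutants they were 608 and 0 without salt and 693 and 79 with salt. In the comparisons with a highest other count of 0 by limma, other splits gave at most 599, 1259, 442 and 1238 genes at an unadjusted p under 0.05, in the order given. The real splits of the WT and arr1,10,12 salt responses follow the scan day.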

How the results depend on the processing

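Fits with the scan day as a block, and of the gene lists without the array labelled ahp2,3,5 salt replicate 3, were chosen after the results were seen, and the other alternatives were planned. Over 650 named gene results, 20796 of 21491 values under the alternatives kept direction and side of the threshold, 657 fell short of it, 38 newly passed and 0 reversed. Over 324 list results, 2923 of 3348 values did so, 265 fell short, 156 newly passed and 4 reversed. The named genes were taken mainly for large called changes in these same data, and many alternatives left out 1 array alone. Their tally therefore favours agreement. The cause of the changes below was not tested unless stated. Replicate numbers did not pair the arrays, since 45 pairs of arrays with the same number had r of -0.271 to 0.208 after the group means were removed (6 above 0.1) and 90 other pairs -0.186 to 0.305 (10 above 0.1). The replicate block changed 5 of 650 named gene results and 4 of 324 list results, and no count of called genes by over 1.5 times. Signal near background limits the folds of dim genes, and the slide block could be fitted for 5 comparisons alone. The comparisons of a mutant with WT under salt and the differences in salt response were among those for which it could not be fitted.

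With normexp and quantile normalization the counts were 3236 for WT salt, 1640 for arr1,10,12 salt, 888 for ahp2,3,5 salt, 1675 and 2294 for arr1,10,12 and ahp2,3,5 against WT without salt, 1741 and 1765 with salt, and 316 and 369 between the mutants without and with salt. With a filter on all 18 arrays 426 genes were called between the mutants with salt, where fewer genes are tested. With the slide as a fixed block the counts were 1845 for WT salt, 2445 for ahp2,3,5 against WT without salt, and 397 and 228 between the mutants. With the scan day as a block 1106 genes were called for arr1,10,12 salt and 1056 for ahp2,3,5 salt. Most of these slide and scan day fits link groups through lone arrays, so a lower count may reflect lost precision. With array weights 3302 were called for ahp2,3,5 salt, with a weight of 0.0452 for replicate 3 of the salt group. With the compared groups alone 497 were called for ahp2,3,5 salt and 14 between the mutants with salt, where fewer arrays set the variance. At an adjusted p under 0.01, a stricter threshold, 353 and 385 were called between the mutants. With no minimum fold, which admits smaller changes, the counts were 15614, 13041 and 10575 for the salt responses of WT, arr1,10,12 and ahp2,3,5, 8986 and 11997 for arr1,10,12 and ahp2,3,5 against WT without salt, 11516 and 11764 with salt, 5908 and 8324 for the differences in salt response, and 4185 and 4008 between the mutants. Without a filter on detection r was 0.873 for the effects of the mutants without salt and 0.64 for the salt responses of arr1,10,12 and WT, and with the filter on all 18 arrays the latter was 0.725. Of the list results 0 passed with an estimated correlation, also without the array labelled ahp2,3,5 salt replicate 3 (19 and 25 at an unadjusted p under 0.05), and 189 passed with fry. Fry reversed 4 lists that had not passed: wall loosening for arr1,10,12 against WT without salt (median -0.01), cytokinin relay (-0.12) and osmolytes (0) for ahp2,3,5 against WT without salt, and nitrate for the difference in salt response of ahp2,3,5 (0.06).

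Leaving out 1 array at a time gave 4775 to 5074 genes for WT salt, 2928 to 3222 for arr1,10,12 salt, and 1134 (without ahp2,3,5 salt replicate 2) to 3427 (without replicate 3) for ahp2,3,5 salt. It gave 2617 to 3109 and 3594 to 3919 for arr1,10,12 and ahp2,3,5 against WT without salt, 2963 to 3470 and 2960 to 3755 with salt, and 1544 to 2255 and 2417 to 3581 for the differences in salt response. Between the mutants it gave 427 to 814 without salt and 497 to 1294 with salt, where 1294 and 1047 were called without ahp2,3,5 salt replicates 1 and 2. It moved the fold of 127 of 650 named gene results by over 1.5 times, 78 of them without ahp2,3,5 salt replicate 3.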

Other observations

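The tests and values here were chosen after the results were seen, apart from the gene lists, which were planned. In WT seedlings some cytokinin genes were called lower with salt, and none of the cytokinin lists passed camera. Of 7 cytokinin oxidases 5 fell, with CKX1, CKX4 and CKX2 at log2 changes of -2.79, -2.38 and -1.69 (camera adjusted p = 0.16). Of 16 synthesis and activation genes 6 fell and 1 rose, with the isopentenyltransferase genes IPT5 (AT5G19040) and IPT3 (AT3G63110) at -3.28 and -1.22 and IPT1 (AT1G68460) at 2.22 (camera adjusted p = 0.17). Of 9 type-A regulators 3 fell, with ARR15 at -1.90 and ARR9 (AT3G57040) at -1.18 (camera adjusted p = 0.05, not under the threshold). In ahp2,3,5 the salt response of this list went the other way, with 4 of 9 higher, among them ARR6 at 2.38 and ARR4 at 1.36 (camera adjusted p = 0.064, and 0.00035 for the difference between the salt responses). The ahp2,3,5 values include the array labelled ahp2,3,5 salt replicate 3, where ARR5 was at -3.86 against -4.20 and -4.11 on replicates 1 and 2. The control levels also differed, with ARR6 at -5.30 ± 0.17 in ahp2,3,5 control and -0.86 ± 0.04 in WT control. Of 9 receptor and other relay genes 1 rose and 1 fell (camera adjusted p = 0.45). With an estimated correlation the adjusted p was 0.72 for the type-A regulators and 0.75 for the oxidases in WT, and 0.72 for the difference.

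Salt in WT also changed genes of other lists that did not pass camera. In proline metabolism the synthesis gene P5CS1 (AT2G39800) rose by 2.12 on the log2 scale (adjusted p = 0.0029), and the galactinol synthase gene GOLS2 (AT1G56600) by 2.37, within a list where 4 of 14 rose and 3 fell. Of 12 abscisic acid metabolism genes 4 rose, the synthesis gene NCED3 (AT3G14440, 1.39) and breakdown genes such as CYP707A1 (AT4G19230, 1.74). Of 21 wall loosening genes 8 rose and 5 fell, with the expansin genes EXPA10 (AT1G26770) at 4.12 and EXPA8 (AT2G40610) at -4.81. Among ion transport genes 1 of 19 rose, the potassium transporter gene HAK5 (AT4G13420, 3.72), and 3 fell, among them HKT1 (-3.15). Of 16 salicylic acid genes 4 rose, SARD1 by 4.33, and 5 fell, WRKY54 with a log2 change of -2.96. Of 10 stomatal genes 4 fell, with KAT1 (AT5G46240) at -1.68 and SPCH (AT5G53210) at -1.22, and of 18 aquaporin genes 5 fell, TIP2;3 with a log2 change of -4.17. Camera adjusted p were 0.6 for osmolytes, 0.099 for abscisic acid metabolism, 0.33 for wall loosening, 0.85 for ion transport, 0.62 for salicylic acid, 0.12 for stomata and 0.16 for aquaporins.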
